A study of Homo sapiens with 11 samples.

How the data were processed

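Samples were grouped by their titles, which give the genotype, the day and a number within the group, as 4 control samples at day 7, 3 control samples at day 14 and 4 GANAB knockdown samples at day 14. Per the labels' protocols, the tissue was fixed in formalin, embedded in paraffin and prepared with a Visium spatial kit. Per the submitters' processing notes, Space Ranger and the mouse build mm10 were used. The header of the deposited table instead names numbered regions of interest, dilutions of antibodies against VIM, HLA-DRA and SMA, and WTA, and its targets carry human symbols. The targets also include a negative control probe, NegProbe-WTX. The target names are thus those of a human probe panel and not of mm10 gene models, and the labels do not describe the table that was deposited. How the deposited values were made is not given in the sources used here.

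Each of the 11 value columns was compared by name with the accession, title, description, source name and characteristics of every sample, as whole words. No name matched, so all 11 columns were left out of every step. The planned gene-level tests, gene list tests and the comparison of both contrasts were not run, and neither depth per sample nor replicate error is given. Which regions came from which animal is not given in the labels.

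Only the names of the targets were used. They were compared, ignoring case, with the current symbols of a human gene name table and with 35 gene lists of 780 different symbols, written before the data were examined. The lists include some mouse symbols, since the host is a mouse. Of the targets, 133 were not current symbols but were RefSeq synonyms of a human gene, and 29 matched neither table. An alternative, chosen after seeing the data, also matched list members through RefSeq synonyms. The genes named are those whose presence or absence describes a list.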

Results

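The study profiled tumours grown in mice from UMUC3, an established human bladder carcinoma cell line. It contrasted tumours labelled WT, called control here, with tumours labelled as a GANAB knockdown. GANAB encodes the catalytic alpha subunit of glucosidase II, the endoplasmic reticulum enzyme that trims glucose from newly attached N-glycans and so controls entry into the calnexin and calreticulin folding cycle. The labels describe 11 samples in 3 groups. The day 7 control group held 4 samples, the day 14 control group held 3, and the day 14 knockdown group held 4. The labels do not say whether the samples of a group came from separate tumours or animals. This design allows a comparison of knockdown with control tumours at day 14, and a comparison of control tumours between day 7 and day 14.

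Neither comparison is reported here, because the values could not be tied to the samples. The table of the series has 11 columns of values, each named by a region number on 1 shared slide, and 0 of the 11 names held the title, genotype, day or any other label of a sample. The order of the columns and the values themselves were not used to assign them. No level of GANAB or of any other gene is therefore given for any group, and no statement is made on whether GANAB was lower in the knockdown tumours.

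The list of measured targets belongs to no single sample and was examined on its own. It held 18677 targets, all with different names, of which 18515 (99.13%) were current human gene symbols. GANAB was among them. The target list covered all 28 genes of a list for N-glycan trimming and the calnexin cycle, which includes PRKCSH, the non-catalytic subunit of glucosidase II, MOGS, the glucosidase that acts before it, and UGGT1, which adds glucose back to misfolded glycoproteins. It covered 31 of 33 genes that build and transfer the lipid-linked oligosaccharide, with ALG1 and ALG11, a pair of mannosyltransferases, absent. All 28 genes of the unfolded protein response and ER chaperone list were present, as were all 23 of the integrated stress response list and all 39 of the proliferation list. Over all lists, 722 of the 749 symbols found in a human gene table were targets. Full coverage of the lists above thus describes the target list and not the tumours.

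Of the 13 protein-coding genes of the mitochondrial genome, 0 were among the targets, while all 37 nuclear genes of the oxidative phosphorylation list were present. The glycolysis list had 17 of 19 members, lacking GAPDH and PGAM1. The symbol PGAM1 is also a synonym of PGAM4, a different gene, which was a target. The cytosolic ribosomal protein list had 44 of 45 members, lacking RPL3.

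Lists of markers of other cell types that a tumour grown in a mouse can hold were matched to different extents. Most of the unmatched members were mouse symbols. The fractions thus reflect how the lists were written more than which cell types the targets cover. The matches are to human symbols, and a shared symbol does not show that transcripts of the mouse host are measured. All 21 endothelial, all 18 fibroblast and all 15 pericyte and smooth muscle markers were among the targets. The macrophage and monocyte list had 23 of 27 members, and the neutrophil list had 16 of 20. The absent members of these 2 lists were written as mouse symbols. For FCGR1 and FCGR3 the targets held FCGR1A and FCGR3A, which carry those names as synonyms. With synonyms, 25 of the 27 macrophage and monocyte members were matched. FCGR1A is itself a member of that list, so the match of FCGR1 to it adds no further target. The NK cell list had 15 of 19 members, the T cell list 17 of 19, the dendritic cell list 11 of 13, the mast cell list 7 of 10 and the erythroid list 8 of 12. Most absent members of these lists were also mouse symbols, but KLRC1, an inhibitory NK cell receptor chain, TRBC2, a T cell receptor constant gene, and TPSB2, a mast cell tryptase, are human symbols. For CD8B1, a mouse symbol, the target CD8B carries the name as a synonym, which makes 18 of 19 for the T cell list with synonyms. CD8B is itself a member of that list, so this match adds no further target. The symbol TPSB2 is also a synonym of TPSAB1, another tryptase gene that was a target. The class I antigen presentation list had 16 of 22 members, and the 6 absent ones were the mouse H2 genes. These counts describe which genes were targeted, not whether any was expressed.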

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

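Of the 780 symbols in the gene lists, 722 were among the targets. Both alternatives were chosen after seeing the data. The number was 730 when RefSeq synonyms were also matched, although a synonym can belong to another gene. Most symbols gained this way matched a target that another list member already named, such as CD8B1 through CD8B and RIGI through DDX58. The larger number therefore counts symbols matched and not further targets covered. The number was 722 of 749 when symbols in neither human table were left out. The symbols left out were all absent from the targets, so only the total changed. That total still holds mouse symbols that are synonyms of a human gene, such as CD8B1. None of the alternatives planned before the data were examined was run (scaling, low-count filters, other tests, the samples in the fit, leaving out each replicate, and the gene list tests), since no column of values was matched to a sample. No paired analysis was possible because the columns carry no replicate number from the labels.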
